A study of Mus musculus with 4 samples.

How the data were processed

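Total RNA from 4 sorted mouse bone marrow fractions was labelled with Cy3 and hybridised to Agilent arrays of 1 design, 1 array per fraction. Per the labels' protocols, RNA was isolated with TRIZOL LS and a micro RNeasy kit, and 10 ng was mixed with Agilent spike-in controls, amplified and labelled with the Quick Amp kit. Lin+ cells were the lineage-positive fraction. The progenitor label names c-Kit-positive lineage-negative cells, while a protocol text shared by all samples gives that fraction as Sca-1-negative and adds lineage-positive cells to its wording, so the exact gate is uncertain. Every sample is labelled replicate 1, and all 4 arrays lay on 1 slide and were scanned together per the file headers, so there were no batches to compare.

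The scanner files hold spot intensity on a linear scale, per the file headers the output of Feature Extraction, which had subtracted background and corrected spatial trends within each array and had not scaled arrays to each other. The submitters' processing notes name Agilent Feature Extraction 10.7.1.1. Its processed signal was the value used, with its own error and its flags for outliers, saturation and signal well above background. A value table of the whole series, deposited by the authors, holds a linear ratio per probe. For 100% of 55246 single-spot probes it equalled the processed signal divided by 1 constant per array within 1%, with constants of 191, 217, 137 and 230 that lie beside the arrays' 75th percentiles (192, 217, 137 and 230). Its scale, centring and direction are therefore known, its column medians were 0.0619, 0.0630, 0.0704 and 0.0738, and it was used as an alternative only.

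Control spots and spots flagged as outliers were left out, and spots of 1 probe were averaged on the log2 scale. Of 55681 probes, 3 with every spot flagged on some array were dropped. No spot was saturated. Each array's log2 signal was scaled by subtracting its 75th percentile over all non-control probes. From 40.9% to 45.9% of probes were detected, and the percentile over probes detected on all arrays (19912) was run as an alternative. A probe not well above background took the higher of its own value and the lowest well-above-background value of its array (-2.94, -3.39, -2.87 and -3.47 in the order of differentiation), and a difference with such a side is a lower bound, given as at least N-fold. Background flags marked 7, 7, 5 and 4 of 308 negative control spots. Among probes printed 10 times and well above background, the median standard deviation between spots was 0.061 to 0.070 on the log2 scale. The median error of a difference by Feature Extraction's estimate was 0.20, and the number of arrays limits the precision further.

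The scanner files name probes by accession, and 26762 probes (48.1%) were named through the RefSeq gene table of assembly GRCm38.p6 without accession versions, giving 20284 genes, 5405 of them with more than 1 probe. The array design uses build mm9, so only names and the order of genes by span were taken from the table, and no coordinates. The probe brightest over the 4 arrays stood for a gene, and background flags and bounds are those of that probe. The remaining 28916 probes include 16180 whose identifier is a genomic interval.

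Comparisons were ST-HSC with LT-HSC, progenitors with ST-HSC, Lin+ cells with progenitors and Lin+ cells with LT-HSC. A gene was called when it differed by at least 2-fold with at least 1 side well above background, bounds included. No test across replicates was possible. Genes highest in 1 fraction had to exceed each other fraction by 4-fold, and genes at every step had to change by 1.5-fold each time. The 32 gene lists (723 listed symbols, 708 on the array, besides lists defined by a family name) were fixed before the data were examined. A list's median difference over its measured members is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays, and a list stood apart below percentile 2.5 or above 97.5. Of 128 results of a list in a comparison, 86 stood apart. The named genes followed a rule fixed with the lists: the sorting genes and lineage antigens, the 6 largest and 6 smallest measured differences and 4 largest bounds each way among genes with agreeing probes, up to 4 called members of each list or all members where 5 or fewer were called, and up to 6 genes per fraction and per direction of the ordered set. Not every gene the rule allows is printed, and some are not reported here.

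Before use, the calling step was tested on simulated data and the list step on random lists of measured genes. For ST-HSC against LT-HSC over 11897 simulated genes, 50 of 50 genes changed 3-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold and 0 of 50 changed 1.5-fold were called, along with 6 unchanged genes. The median absolute error of the unchanged simulated genes was 0.15 on the log2 scale. With so small an error, these numbers of calls at a 2-fold limit were largely set in advance. They check that the calling step runs as written. They do not show how well changes are found in dim genes, among bounds, after amplification or between mice. Of 200 random null lists drawn from the measured differences of ST-HSC from LT-HSC, 4% fell outside the limits.

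Alternatives chosen with the lists were normexp background correction with an offset of 50, median, quantile and spike-in scaling, the percentile over detected probes, the deposited table, genes well above background on both arrays only, no background filter, a doubled threshold, the mean of a gene's probes, agreeing probes only, curated mRNA accessions only, and leaving out saturated spots. The files used hold no mean spot signal, so normexp was run on median spot and median background signals. The median gene of a comparison is over genes measured on both arrays, except for list medians given relative to it, where it is over all compared genes with bounds included and unresolved ones at 0 (0.02, 0.17, -0.33 and -0.15 in the order of the comparisons before any alternative). After seeing the data, 4 more were added: centring each comparison on its median gene, correcting differences for genomic span, matching random lists on span, and leaving out the progenitor array. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.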

Results

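Gene expression was measured in 4 fractions sorted from the bone marrow of 8-week-old female C57BL6 mice, with 1 single-colour Agilent array per fraction. The fractions follow the order of blood cell differentiation that the series is about. Long-term haematopoietic stem cells (LT-HSC) were CD34-negative cells that carried c-Kit and Sca-1 and lacked lineage markers. Short-term stem cells (ST-HSC) differed from them in carrying CD34. Progenitors were c-Kit-positive and lineage-negative, and the differentiated fraction was lineage-positive (Lin+). From 40.9% to 45.9% of the 55678 probes on each array were well above background, and 11667 to 12470 of 20284 named genes were. The 75th percentile of the signal, to which each array was scaled, lay at 192 intensity units in LT-HSC, 217 in ST-HSC, 137 in progenitors and 230 in Lin+ cells. Because each fraction had 1 array, no difference below has a replicate check and no p-value is given. The ± values are the spot error that Feature Extraction computed, which covers the measurement of a spot and not the spread between mice. It is an estimate rather than a spread between repeated spots, and its median for a value was 0.14 on every array. All differences are on the log2 scale unless a fold is named. Where a list's count is given in 1 direction only, 0 members reached 2-fold in the other.

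The genes of the surface proteins used for sorting were measured first. Cd34 signal lay 7.34 above the array's 75th percentile in LT-HSC, 8.53 in ST-HSC, 7.51 in progenitors and 3.26 in Lin+ cells, so Cd34 RNA was present in the CD34-negative fraction and was higher in the CD34-positive stem cells by 1.19 ± 0.20. Kit, the receptor of stem cell factor, gave 5.63, 5.004, 4.42 and 1.67 in that order. Ly6a, which encodes Sca-1, gave 4.52, 3.12, 2.28 and 4.51. Among common lineage antigens, Ptprc, which encodes CD45, gave -0.08, 0.73, -1.15 and 2.36. The brightest probe for Itgam gave 4.83 to 5.17 and that for Cd4 2.39 to 2.91 across all 4 arrays, with no difference of 2-fold between any compared pair. With the mean of Itgam's probes, its difference of ST-HSC from LT-HSC moved to 0.44, by more than the spot error allows. The specificity of these probes was not examined, so their level signal does not show that the RNA was level. Across the 13761 genes well above background on at least 1 array, Pearson's r, a value across genes that are not independent replicates, was 0.952 between LT-HSC and ST-HSC, 0.939 between ST-HSC and progenitors and 0.878 between progenitors and Lin+ cells. LT-HSC and Lin+ cells gave 0.806.

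**Figure D1:**
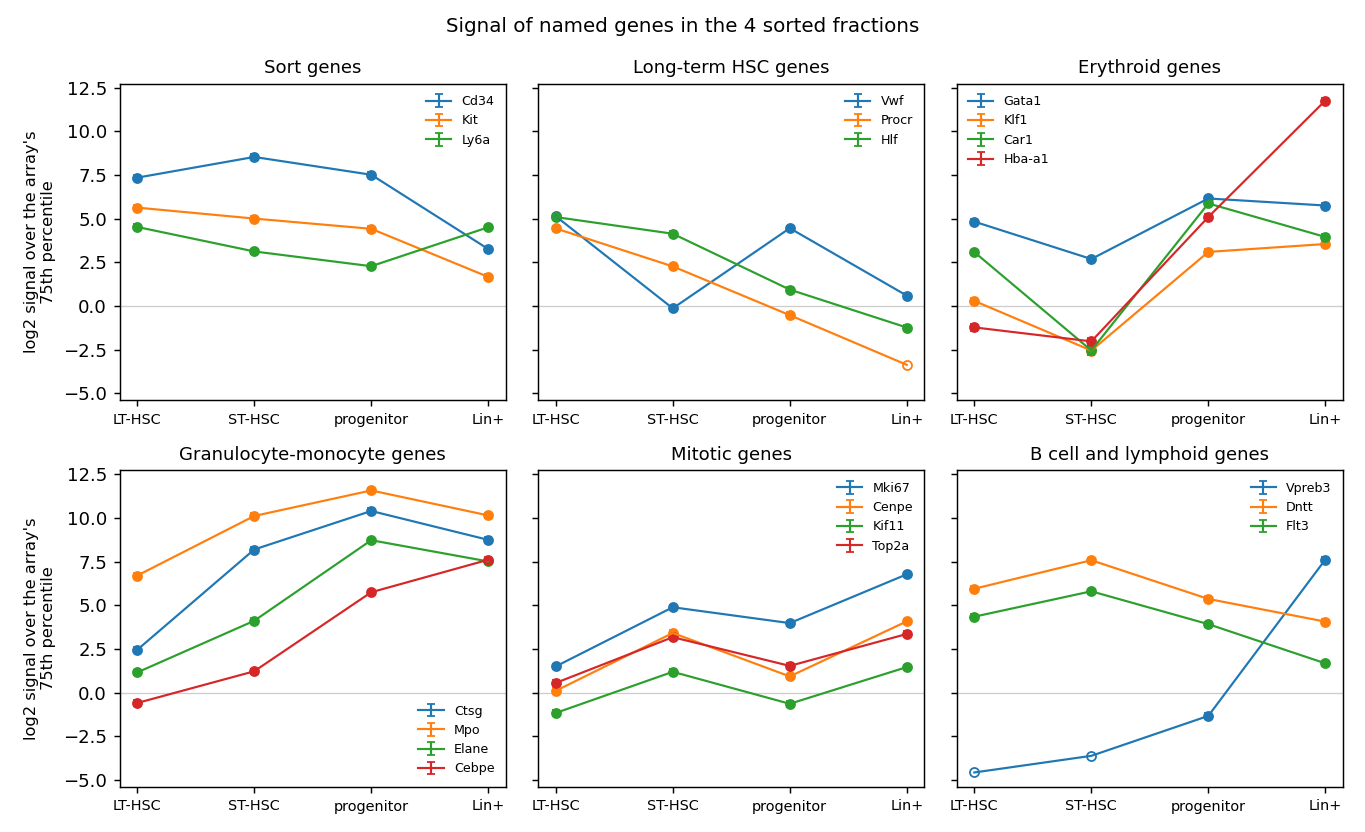
Signal of named genes in the 4 fractions, 1 array each, on the log2 scale over the array's 75th percentile; filled points were well above background, open points were not, and bars are the spot error. Cd34 peaks at 8.53 in ST-HSC, Vwf and Car1 dip in ST-HSC, and Hba-a1 reaches 11.76 in Lin+ cells.

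The comparison of ST-HSC with LT-HSC set CD34-positive against CD34-negative stem cells. Long-term stem cell and megakaryocyte genes were lower in ST-HSC, and genes of granulocyte-monocyte progenitors and of cell division were higher. In ST-HSC, 22 of 25 measured long-term HSC genes were at least 2-fold lower and 0 were higher, with a list median of -2.26. Vwf, which encodes the platelet adhesion protein von Willebrand factor, differed by -5.27 ± 0.21, Sult1a1 by -4.96 ± 0.22 and Tgm2 by -4.30 ± 0.20. Hoxb5 was not well above background in ST-HSC and was at least 16.3-fold lower. Megakaryocyte genes were lower for 15 of 19 (median -2.18), among them Pf4, platelet factor 4, at -3.80 ± 0.20 and Treml1 at -2.99 ± 0.20. Of 25 erythroid genes, 14 were lower and 1 was higher (median -1.35): Car1, a red cell carbonic anhydrase, differed by -5.63 ± 0.28 and the water channel gene Aqp1 by -3.79 ± 0.20. Hox genes were lower for 9 of 14, with Hoxb2 at -3.05 ± 0.25. Within the list of stem and progenitor transcription factors 11 of 32 were lower and 2 were higher, with Prdm16 at -2.26 ± 0.21 and Irf8 at 2.89 ± 0.20.

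Granulocyte-monocyte progenitor genes were at least 2-fold higher in ST-HSC for 17 of 21, with a median of 2.07. Ctsg, the neutrophil protease cathepsin G, was higher by 5.74 ± 0.20 and Mpo, myeloperoxidase, by 3.41 ± 0.20. Mitotic genes were higher for 36 of 40 (median 1.77), including Mki67 at 3.39 ± 0.20 and the kinesin gene Cenpe at 3.31 ± 0.21. S phase genes were higher for 20 of 35 (median 1.07), including Pola1, a DNA polymerase subunit, at 2.13 ± 0.20, and no member of either list was 2-fold lower. Among inhibitors of the cell cycle and quiescence genes 8 of 25 were lower and 2 higher, with Cdkn1c, which encodes the inhibitor p57, at -3.11 ± 0.21. Lymphoid priming genes were higher for 6 of 14 and lower for 0, with Cd48 at 1.98 ± 0.20, Satb1 at 1.76 ± 0.20 and Dntt, terminal transferase, at 1.63 ± 0.20. Of 24 genes of ABC transporters and detoxification 6 were lower and 0 higher, with Aldh1a1 at -4.40 ± 0.21. Immediate-early and heat shock genes were lower for 7 of 26 and higher for 1. Smaller shifts of whole lists, in which few or no members reached 2-fold, were seen for ribosome biogenesis genes (median 0.43), cholesterol synthesis genes (-0.35) and interferon-stimulated genes (-0.40).

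Among the largest single differences, F13a1, which encodes a subunit of coagulation factor XIII and was on the monocyte and macrophage list, was higher in ST-HSC by 6.46 ± 0.26 and Slpi by 4.32 ± 0.21. Cavin2 was lower by a difference of -5.34 ± 0.22 and Ehd3 by -4.48 ± 0.28. Cyp26b1, which encodes an enzyme that degrades retinoic acid, was not well above background in ST-HSC and was at least 84.1-fold lower, and Evc2 at least 46.0-fold lower. Mcpt8, a basophil protease gene of the basophil, mast cell and eosinophil list, was at least 15.6-fold higher. In all, 733 genes were at least 2-fold higher and 1137 lower among 12621 compared, so that 39.2% of the called genes were higher. The median gene differed by 0.03. The percentile over probes detected on all arrays lowered that share to 34.7% and scaling to the spike-in controls raised it to 63.0%, and counting genes well above background on both arrays alone gave 545 higher and 747 lower.

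The next step set c-Kit-positive lineage-negative progenitors, whose sample label does not name Sca-1, against ST-HSC. Erythroid, megakaryocyte, basophil and neutrophil genes were higher in progenitors, while lymphoid priming, interferon-stimulated and mitotic genes were lower. Erythroid genes were at least 2-fold higher for 26 of 31 and lower for 1, with a median of 3.47. Car1 was higher by 8.41 ± 0.28, Hba-a1 by 7.12 ± 0.25 and Klf1, a red cell transcription factor, by 5.64 ± 0.30, and Rhd was at least 489-fold higher against a signal not well above background in ST-HSC. Heme synthesis genes were higher for 11 of 13 (median 1.497), with Cpox at 2.29 ± 0.20. Megakaryocyte genes were higher for 13 of 20 and lower for 1, or 2 with the median gene set to 0 (median 1.71), led by Pf4 at 5.42 ± 0.20 and Vwf at 4.59 ± 0.21. Genes of basophils, mast cells and eosinophils were higher for 13 of 17 and lower for 0 (median 4.197), among them Prg2, eosinophil major basic protein, at 7.61 ± 0.21 and the basophil protease gene Prss34 at 6.12 ± 0.30. Granulocyte-monocyte progenitor genes were higher for 16 of 21 (median 1.63), with Elane, neutrophil elastase, at 4.61 ± 0.20. Neutrophil genes were higher for 13 of 21 and lower for 2, with S100a8 at 5.73 ± 0.21 and Camp at 4.08 ± 0.21, and monocyte and macrophage genes were higher for 7 of 18, with Cd14 at 3.39 ± 0.21, a list that no longer stood apart with normexp (percentile 97.3) or without background filter and floor (95.9).

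Lymphoid priming genes were at least 2-fold lower in progenitors for 8 of 14 and higher for 0 (median -1.12), with Dntt at -2.21 ± 0.20, Satb1 at -2.10 ± 0.20 and Flt3, a cytokine receptor of early lymphoid cells, at -1.88 ± 0.20. Interferon-stimulated genes were lower for 14 of 29 and higher for 0 (median -0.82), with the antiviral genes Oas2 at -2.72 ± 0.21, Oasl2 at -2.49 ± 0.20 and Ddx58 at -2.07 ± 0.20. Long-term HSC genes were lower for 9 of 20 and higher for 3, or 1 with the median gene set to 0, from Hlf at -3.20 ± 0.21 and Procr at -2.79 ± 0.21 to Vwf. Mitotic genes were lower for 15 of 40 and higher for 0 (median -0.47), among them Cenpe at -2.48 ± 0.21, Kif11 at -1.83 ± 0.22 and Kif23 at -1.81 ± 0.21. In contrast to these, S phase genes had a median of 0.52 with 4 of 35 higher, or 1 with the median gene set to 0, and 1 lower, and their median was inside the range of random lists (percentile 95.9). Hox genes were lower for 5 of 12, with Hoxa5 at -2.10 ± 0.30, but without background filter and floor the list's median relative to the median gene turned to 0.0308. Oxidative phosphorylation genes were higher for 13 of 77, a number that became 4 with that centring, and ribosome biogenesis genes were higher for 4 of 28, or 1 when centred. Among inhibitors of the cell cycle and quiescence genes 6 of 25 were lower and 1 higher, or 10 and 0 when centred. The heat shock gene Hspa1a was higher by 5.47 ± 0.22, the largest difference among the 9 immediate-early and heat shock genes of 26 that were higher, while 3 were lower. The median of that list, 0.32, was inside the range of random lists (percentile 20.8).

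The differences that use the progenitor array also followed gene length. Over 12614 genes ordered by genomic span, the median difference of progenitors from ST-HSC went from 0.42 in the shortest of 5 equal groups to -0.15 in the longest. Spans came from another assembly than the array's build and served only to order genes. For Lin+ cells against progenitors the median difference went from -0.56 to 0.00. It stayed between -0.01 and 0.05 for ST-HSC against LT-HSC and between -0.19 and -0.10 for Lin+ cells against LT-HSC. Bounds were included in these medians and unresolved genes entered as 0, so the 0.00 is such an entry and not a measured difference. Among random lists matched on span as well as expression, the mitotic, interferon-stimulated and lymphoid priming lists still stood apart in progenitors (percentile 0 for each). Chromatin regulators, 6 of 51 lower and 1 higher with a median of -0.03, did not (percentile 5.77, against 1.11 without span matching).

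Outside the lists, Sphk1, sphingosine kinase, was higher in progenitors by 8.80 ± 0.26 and the amino acid transporter gene Slc38a5 by 7.39 ± 0.23. Vldlr differed by -4.34 ± 0.24 and Ptgs2, which encodes cyclooxygenase 2, by -3.39 ± 0.31. In all, 1267 genes were at least 2-fold higher and 1284 lower among 12614 compared, 49.7% of them higher. The median gene differed by 0.21, and the share of higher calls depended on the scaling: it was 33.1% with the median gene at 0, 36.7% after median scaling, 29.7% when the percentile was taken over probes detected on all arrays, 38.9% after quantile normalization and 13.7% with the spike-in controls. That last scaling put the median gene at -0.42 and turned the S phase median below 0. It shifts all genes alike, so this turn says nothing about the place of the S phase list among the other genes.

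**Figure D2:**
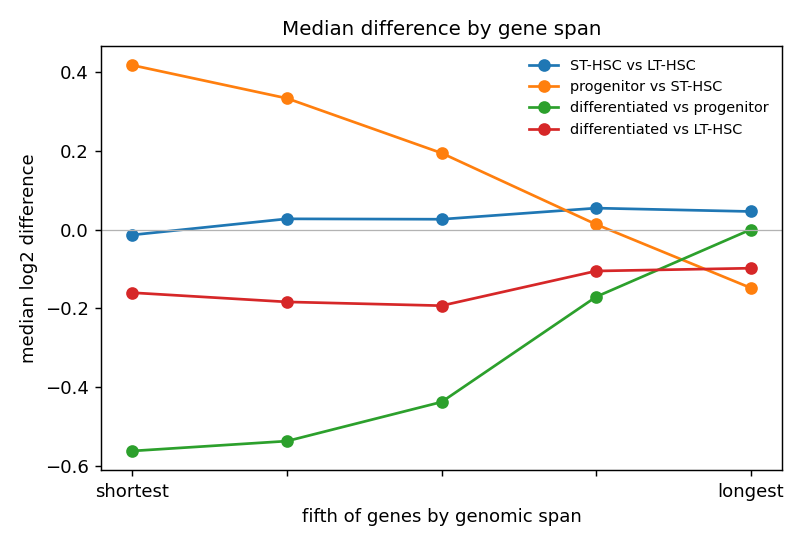
Median log2 difference of genes in 5 equal groups by genomic span, from shortest to longest, for each of the 4 comparisons. Bounds are included and unresolved genes count as 0. The line of progenitors against ST-HSC falls from 0.42 to -0.15 and that of Lin+ cells against progenitors climbs from -0.56 to 0.00, while the other lines run from -0.01 to 0.05 and from -0.16 to -0.10.

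The comparison of Lin+ cells with progenitors covered the passage to mature cells. Neutrophil, B cell, T and NK cell and erythroid genes were higher in Lin+ cells, and megakaryocyte and ribosome biogenesis genes were lower. Neutrophil genes were at least 2-fold higher for 27 of 28, with a median of 6.52, including the granule protein genes Ltf, lactoferrin, at 11.26 ± 0.24 and Ngp at 10.22 ± 0.23. B cell genes were higher for 25 of 25 (median 5.33): Vpreb3 differed by 8.95 ± 0.24 and Ly6d by 7.85 ± 0.24. T and NK cell genes were higher for 17 of 24 and lower for 2, or 1 when centred, with Cd2 at least 295-fold and Cd3d at least 64.4-fold higher. Erythroid genes were higher for 24 of 32 and lower for 2 (median 2.43), with Alas2, the first enzyme of heme synthesis in red cells, at 10.05 ± 0.23 and Slc4a1, the anion exchanger band 3, at 9.49 ± 0.22. Heme synthesis genes were higher for 11 of 13 and lower for 1, or 0 when centred, with Slc25a37 at 4.41 ± 0.20 and Fech at 3.41 ± 0.20. MHC class II genes were higher for 5 of 9, with H2-Aa at 5.67 ± 0.24 and Cd74 at 5.47 ± 0.21. Monocyte and macrophage genes were higher for 15 of 22 and dendritic cell genes for 10 of 14. Plasma cell genes were higher for 6 of 12 and lower for 1, and did not stand apart when only values well above background were used (percentile 80.5). Interferon-stimulated genes were higher for 11 of 30 and lower for 2, or 1 when centred, with Rsad2 at 6.09 ± 0.22. Mitotic genes were higher for 22 of 40 and lower for 0 (median 1.17), with Cenpe at 3.15 ± 0.21 and Mki67 at 2.79 ± 0.20, in a comparison that includes the array with the length trend. Inhibitors of the cell cycle and quiescence genes were higher as well, for 11 of 25 with 1 lower, or 15 and 0 when centred (median 0.83), with Foxo1 at 3.22 ± 0.21.

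Megakaryocyte genes were at least 2-fold lower in Lin+ cells for 14 of 20 (median -1.73) and higher for 2, or 4 with the median gene at 0: Pf4 differed by -6.24 ± 0.20 and Treml1 by -5.84 ± 0.22. Long-term HSC genes were lower for 11 of 19 and higher for 2, or 9 and 4 with the median gene at 0, and without background filter and floor the list no longer stood apart (percentile 11.1). Hox genes were lower for 5 of 7 measured of 39 on the array, or 3 when centred, and did not stand apart without filter and floor (percentile 5.56) or after correction for genomic span (3.80), an alternative chosen after the data were seen. Cd34 was lower by a difference of -4.25 ± 0.20 and Kit by -2.75 ± 0.20, while Ly6a was higher by 2.23 ± 0.20. Ribosome biogenesis genes were lower for 26 of 28 (median -1.85), with Gar1 at -2.51 ± 0.20 and Polr1b, a subunit of RNA polymerase I, at -2.49 ± 0.21. Cytosolic ribosomal protein genes were lower for 71 of 78 with a median of -1.25, and oxidative phosphorylation genes for 51 of 77 with a median of -1.11, and 1 gene of each list was higher. The median gene itself differed by -0.42 among genes measured on both arrays. With that median set to 0 the ribosomal protein count was 15 and the oxidative phosphorylation count 14, and the ribosome biogenesis count was 22. After quantile normalization the ribosomal protein list no longer stood apart (percentile 2.67). Stem and progenitor transcription factors were lower for 15 of 33 and higher for 3, with Meis1 at -3.58 ± 0.21 and Gata2 at -3.17 ± 0.20, and the list was inside the random range (percentile 3.61).

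In this comparison 1883 genes were at least 2-fold higher and 3429 lower among 12990, 35.4% of them higher. The share of higher calls was 31.9% after median scaling, 60.2% with the median gene at 0, 58.5% when the percentile was taken over probes detected on all arrays, 45.6% after quantile normalization and 71.2% with the spike-in controls. With the median gene at 0, the counts were 2772 higher and 1833 lower.

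**Figure D3:**
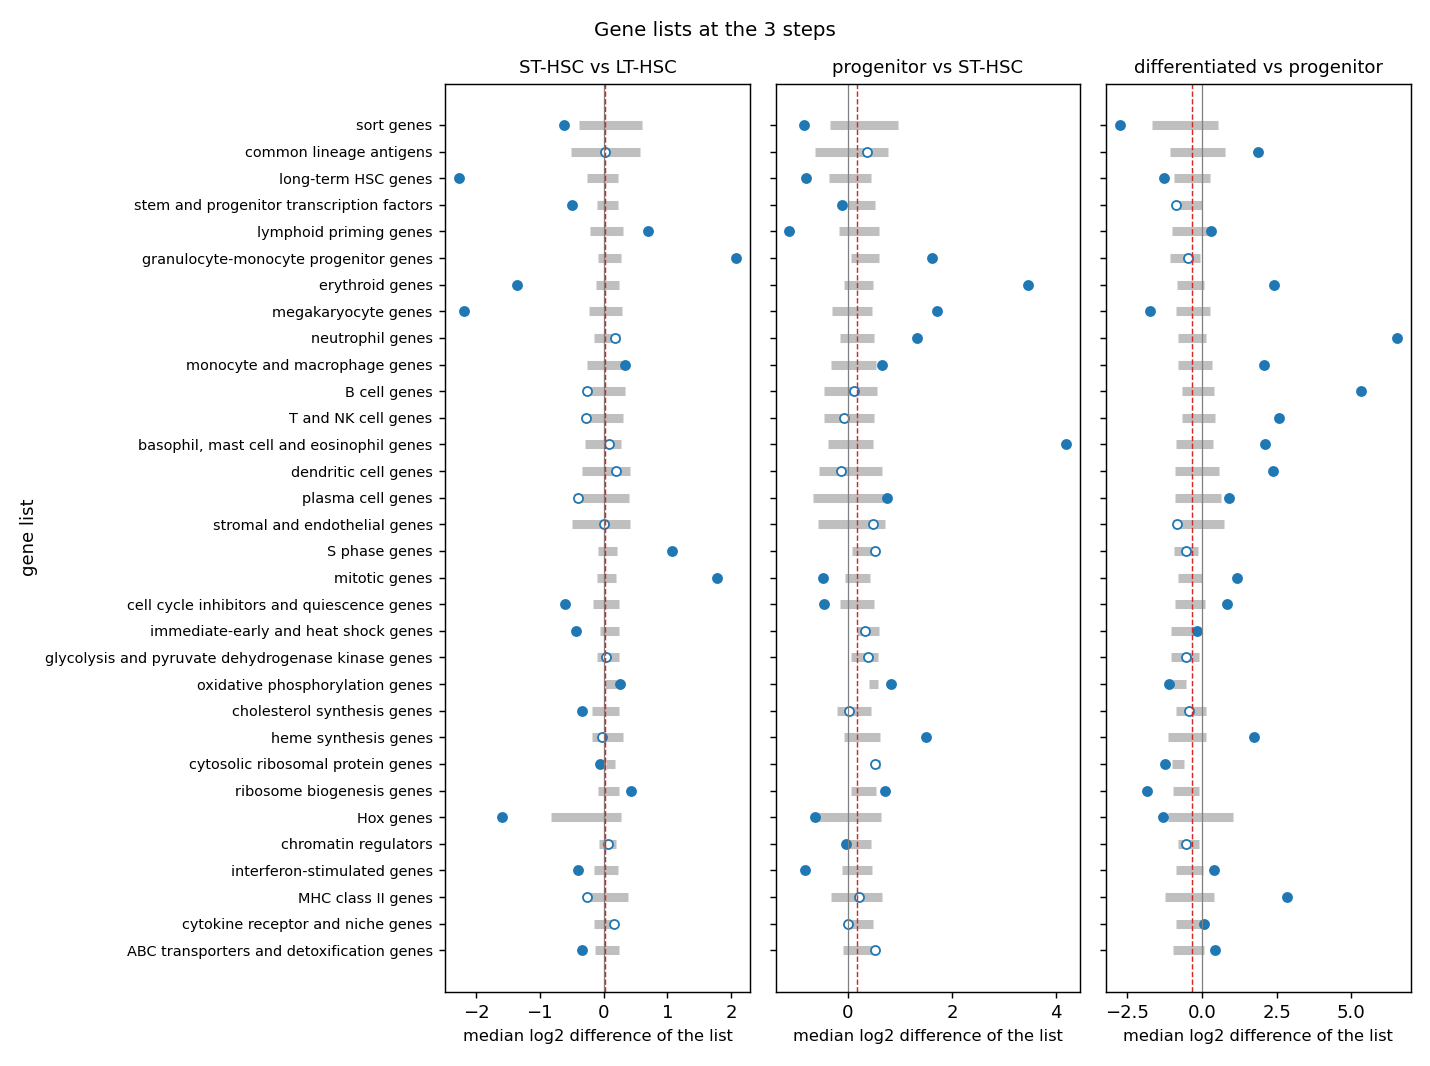
Median log2 difference of each of 32 gene lists (points) at the 3 steps, with the central 95% of 10000 random lists matched on expression (grey bars) and the median of all compared genes (dashed line); filled points lie outside the bars. The panels have different scales, and the neutrophil list reaches 6.52 in Lin+ cells against progenitors, and the mitotic list is at 1.77, -0.47 and 1.17 in the 3 panels.

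Across the ends of the order, Lin+ cells against LT-HSC, erythroid, heme synthesis and mitotic genes were higher, and long-term HSC, Hox and megakaryocyte genes were lower. Hba-a1, an alpha globin gene, was higher by 12.98 ± 0.23, Ltf by 12.32 ± 0.33 and Camp by 11.76 ± 0.22. Robo4 differed by -6.78 ± 0.26. Procr, the endothelial protein C receptor gene, was not well above background in Lin+ cells and was at least 224-fold lower, and Esam at least 202-fold lower. Long-term HSC genes were lower for 23 of 25 (median -4.06) and Hox genes for 14 of 14 (median -3.28), with 0 higher in either list. Megakaryocyte genes were lower for 13 of 20 and higher for 3 (median -2.39). Mitotic genes were higher for 37 of 40 and lower for 1, or 0 when centred (median 2.36), and S phase genes for 17 of 35 (median 0.98), with Mki67 at 5.27 ± 0.20 and Rrm2, a ribonucleotide reductase subunit, at 3.69 ± 0.20. Heme synthesis genes were higher for 13 of 13 and erythroid genes for 28 of 32. Cytosolic ribosomal protein genes had a median of -0.81 with 15 of 77 lower, or 1 with the median gene at 0, and 1 higher. Cholesterol synthesis genes were lower for 9 of 24 (median -0.75). Oxidative phosphorylation, glycolysis, interferon-stimulated, immediate-early, and chromatin regulator lists had medians inside the random range (percentiles 66.3, 15.3, 18.1, 10.8 and 22.8). In all, 2144 genes were higher and 3086 lower among 13285 compared, 41.0% of them higher. That share was 51.2% with the median gene, which differed by -0.21, set to 0, 30.7% after median scaling and 55.3% with the spike-in controls.

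Genes at least 4-fold above each of the other 3 fractions numbered 148 in LT-HSC, 24 in ST-HSC, 61 in progenitors and 588 in Lin+ cells. They numbered 34, 1, 5 and 236 when only values well above background were used, and 43, 0 and 6 in the first 3 fractions with normexp. The LT-HSC set held 12 of 26 long-term HSC genes, and Cyp26b1, 41.3-fold above the next fraction, led it, followed by Evc2 (at least 32.1-fold), Clip3 (at least 25.4-fold) and Lor (at least 18.3-fold). In ST-HSC the margins were smaller, with Xkr6 first at 9.20-fold or more. In progenitors Dnah1 led at 11.96-fold or more, and Mt2, a metallothionein gene measured on all arrays, was 10.4-fold above the next fraction. The Lin+ set held 25 of 28 neutrophil genes, 22 of 25 B cell genes and 18 of 33 erythroid genes, and was led by Unc93a2, Ltf and Retnlg.

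Along the order of fractions, 61 genes were at least 1.5-fold higher at every step and 161 at least 1.5-fold lower. C3, a complement component gene, went from -0.78 in LT-HSC through 1.69 and 5.17 to 7.94 in Lin+ cells, and Cebpe, a granulocyte transcription factor gene, from -0.59 through 1.23 and 5.75 to 7.61. Pram1, Prg2, Mrgpra2a and Mrgpra2b also increased at each step, from signals not well above background in LT-HSC. Procr went from 4.44 through 2.27 to -0.52 in progenitors and was not well above background in Lin+ cells. Nkx2-3, Bdh2 and F11r did likewise, and Col16a1 and Eya2 decreased at each step while measured on all arrays. Of the 26 long-term HSC genes 9 were in the decreasing set. Each step shares an array with the next, so an error on 1 array enters both steps.

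A different probe of the same gene gave the same direction for 289 of 301 called genes (96.0%) in ST-HSC against LT-HSC, 494 of 536 (92.2%) in progenitors against ST-HSC, 1161 of 1222 (95.01%) in Lin+ cells against progenitors and 1049 of 1121 (93.6%) in Lin+ cells against LT-HSC. The other probe was itself at least 2-fold different for 74.4%, 63.1%, 74.1% and 72.2%. These shares describe probe error only. Globin and Mrgpra genes have near-identical copies, and the specificity of their probes was not examined, so single members are uncertain.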

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

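Chosen only after the result was seen were the tests of cycling cells, run against the median gene before matched lists and with the inhibitor list added later, the span correction, and the tests of RNA integrity and of mixed cells, which left the question open when both sources were tested as 1 and were divided by source and then by list after the values were known, and the intervals named by position.

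Probes whose identifier is a genomic interval of build mm9 were outside every comparison of named genes above, and part of them gave signal well above background. Among 4607 such intervals, 39.3% were well above background in LT-HSC, 46.5% in ST-HSC, 43.7% in progenitors and 49.4% in Lin+ cells, against 2.27%, 2.27%, 1.62% and 1.30% of the negative control spots. The 4607 intervals were covered by 16180 probes, and the probe brightest over the 4 arrays stood for each. Control shares are of single spots, and taking the brightest probe raises the interval shares, so they are not like for like. Intervals at least 4-fold above each other fraction numbered 23, 18, 42 and 60 in that order. The leading intervals were chromosome 3 from 152810906 to 152815072 in LT-HSC (10.98-fold or more), chromosome 12 from 16003706 to 16022581 in ST-HSC (10.2-fold or more), chromosome 17 from 27703181 to 27716306 in progenitors (25.4-fold or more) and chromosome 10 from 69819062 to 69871640 in Lin+ cells (109-fold or more). In ST-HSC against LT-HSC 139 of 2258 compared intervals were at least 2-fold higher and 125 lower. The counts were 401 and 193 of 2370 in progenitors against ST-HSC and 248 and 494 of 2503 in Lin+ cells against progenitors. In Lin+ cells against LT-HSC they were 335 and 298 of 2439. These counts use the main scaling only, and among named genes the share of higher calls in comparisons with progenitors depended on the scaling. What these intervals transcribe was not analysed here, and no explanation was tested.

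Mitotic genes were lower in progenitors than in ST-HSC. The tables argue against genomic span as the whole cause. Among random lists matched on expression and span, the list's median of -0.47 was at percentile 0 (random range -0.03 to 0.45). Background or scaling that depends on signal would move lists of like expression nearly alike, so this place also argues against it. The list stayed at percentile 0 after quantile normalization and after normexp, but the matching largely set that in advance, so it adds little. Fewer cycling cells in the progenitor fraction stay open: the S phase list did not fall with the mitotic list, as it lay 0.35 above the median of all compared genes (95% bootstrap interval over its members 0.21 to 0.48) and the mitotic list at -0.64 (-1.20 to -0.23). But lists matched on expression had medians of 0.09 to 0.53, which enclose the S phase median of 0.52 (percentile 95.9). It was also inside with lists matched on span (percentile 96.6), and outside after correction for span (97.9). The inhibitor and quiescence list, 10 of 25 lower and 0 higher when centred, also runs against fewer cycling cells, but that list was higher together with the mitotic list in Lin+ cells against progenitors (11 of 25, with 1 lower), so its direction alone does not decide. Lower RNA integrity on the progenitor array may contribute and stays open too: longer mitotic genes differed more (Spearman's rho across genes -0.48, interval -0.71 to -0.18), the array is the group, transcript lengths were not used here, and a difference between the fractions was not tested and stays open as well.

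Erythroid and megakaryocyte genes were lower in ST-HSC than in LT-HSC, and 29 of them were set against other cells in the LT-HSC sort. The tables argue against cells with the profile of the Lin+ array, which the lineage-negative gate would remove: the 29 genes needed a median of 116% of that array's signal and the 14 erythroid genes alone 9.98%, while 8 abundant erythroid genes, Hba-a1, Slc4a1 and Alas2 among them, allowed 0.0499%. For progenitor cells, which a Sca-1 gate would reduce, the 29 genes needed a median of 67.3%, and 8 abundant erythroid genes allowed a median of 44.6%. In both tests the 8 genes were outside the 29 because they were not called lower in ST-HSC, so the change itself parted needed from allowed. The lists parted: the 15 megakaryocyte genes needed 110%, 9 of them over 100%, which argues against cells with the whole progenitor profile as their cause. The 14 erythroid genes needed a median of 13.9%, 12 of them no more than the median allowed. Hba-a1 and Hba-a2, however, allowed 1.25% and 1.17%, less than any of these 14 genes needed (lowest Cldn13, 2.33%). That goes against cells with the whole progenitor profile, but it rests on globin probes of unexamined specificity, so progenitor cells stay open for the erythroid part. A subset of progenitors and platelets carried by LT-HSC were not tested, and a difference between the CD34-negative and CD34-positive fractions stays open, also untested.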

How the results depend on the processing

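Chosen after seeing the data were centring on the median gene, the correction for genomic span, random lists matched on span, and leaving out the progenitor array. No paired analysis was possible because each fraction had 1 array. Of 86 list results that stood apart, 67 did so with the same sign in every setting, 16 were lost without a change of sign in some and 4 changed sign in some. Plasma cell genes in progenitors against ST-HSC did both, and 83 to 88 stood apart in any 1 setting. Many settings test the lists little, because a constant shift of an array moves a list and its random lists nearly alike. These are median, spike-in and detected-percentile scaling, the deposited table and centring, and a doubled threshold does not enter a percentile. All 128 list results stayed the same with spike-in scaling and 127 with median scaling. Lost in progenitors against ST-HSC were chromatin regulators (3 settings), plasma cell genes (2), monocyte and macrophage genes (2) and stem and progenitor transcription factors (1). Lost in Lin+ cells against progenitors were lymphoid priming genes (5), cytokine receptor and niche genes (3), Hox genes (2), immediate-early and heat shock genes (2), and long-term HSC, ribosomal protein, plasma cell and common lineage antigen genes (1 each). Lost in Lin+ cells against LT-HSC were lymphoid priming genes (3), and plasma cell genes, common lineage antigens and stem and progenitor transcription factors (1 each). All 4 sign changes (against the median gene) came without filter and floor. In ST-HSC against LT-HSC these were monocyte and macrophage (-0.0905) and ribosomal protein genes (0.141, still at percentile 0). In progenitors against ST-HSC they were plasma cell (-0.00424) and Hox genes (0.0308). Over named genes and settings, 7662 results stayed called or uncalled, 12 became called and 380 lost a call, 136 only by the doubled threshold. The other 13, of uncalled antigens Itgam, Cd3e, Cd4 and Cd8a, moved by more than spot error allows. Counts stayed within 1.5 times in 181 cases and moved further in 50. Leaving out saturated spots removed nothing and so tests nothing. The causes of the moves below were not tested, except where a stricter or looser rule sets the count. The spike-in controls put the median gene at 0.34, -0.42, 0.19 and 0.08 in the order of the comparisons. Normexp, which also replaced the processed signal by median spot signals and added an offset, moved 10 of the counts, the requirement on both arrays 6, and dropping filter and floor 7.

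With normexp, ST-HSC against LT-HSC gave 452 higher and 612 lower, progenitors against ST-HSC 615 and 724, and Lin+ cells against progenitors 2072 lower, while genes highest in LT-HSC, ST-HSC and progenitors numbered 43, 0 and 6, and genes increasing and decreasing at every step 40 and 98. Taking the percentile over detected probes gave 797 higher in progenitors against ST-HSC and 1912 lower in Lin+ cells against progenitors. Spike-in scaling gave 1326 higher in ST-HSC against LT-HSC, 505 higher and 3183 lower in progenitors against ST-HSC, 3342 higher and 1352 lower in Lin+ cells against progenitors, and 42 genes highest in ST-HSC. Requiring signal well above background on both arrays gave 747 lower in ST-HSC against LT-HSC, 34, 1, 5 and 236 genes highest in each fraction in order, and 99 decreasing at every step. Without filter and floor, ST-HSC against LT-HSC gave 1166 and 1763, progenitors against ST-HSC 2064 higher, the first 3 fractions 289, 85 and 130 genes, and the decreasing set 286. Doubling the threshold to 4-fold gave 132 and 374, 371 and 230, 803 and 775, and 1019 and 1194 in the 4 comparisons. The limit for 1 fraction was then 8-fold, with 34, 3, 12 and 326 genes. That per step rose only from 1.5-fold to 2-fold, with 29 genes increasing and 52 decreasing. Centring on the median gene gave 1833 lower in Lin+ cells against progenitors. Without the progenitor array there were fewer conditions to meet, and LT-HSC had 258 genes, ST-HSC 38, the increasing set 322 and the decreasing set 698.

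Matching random lists on span ended 3 list results: chromatin regulators in progenitors against ST-HSC (percentile 5.77), and lymphoid priming genes in Lin+ cells against progenitors (97.4) and against LT-HSC (96.96). ABC transporter genes in progenitors against ST-HSC (98.3) and stem and progenitor transcription factors in Lin+ cells against progenitors (2.14) newly stood apart.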

Other observations

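The lists described here were picked for description after their values were seen. Among cytokine receptor and niche genes in ST-HSC against LT-HSC, 6 of 35 were at least 2-fold higher and 7 lower (median 0.16, percentile 93.0). Csf1r, the receptor of macrophage colony-stimulating factor, differed by 2.28 ± 0.20, while Epor, the erythropoietin receptor, differed by -3.50 ± 0.21 and Tgfbr3 by -2.58 ± 0.21. In progenitors against ST-HSC, Epor was higher by 5.52 ± 0.21. MHC class II genes were lower in ST-HSC than in LT-HSC for 3 of 8, and their median of -0.25 was inside the random range (percentile 3.14): Cd74 differed by -3.34 ± 0.21, H2-Aa by -3.20 ± 0.31 and H2-Eb1 by -2.72 ± 0.21, and each was higher again in progenitors, by 1.56, 1.30 and 1.31. In ST-HSC against LT-HSC, B cell genes, which include Cd74 and H2-Aa, were lower for 4 of 13, T and NK cell genes for 5 of 16 and plasma cell genes for 3 of 10, with 0 higher in each, and their medians were also inside the random range (percentiles 5.46, 3.79 and 3.59), though each of these 4 lists was outside it in at least 1 alternative.

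Glycolysis genes did not stand apart in any comparison (percentiles 34.1, 56.5, 61.1 and 15.3), and 2 of 26 were higher and 4 lower in ST-HSC against LT-HSC, with Eno2 at -1.91 ± 0.26 and Hk3 at 1.93 ± 0.20. Stromal and endothelial genes, of which 8 of 19 were measured in ST-HSC against LT-HSC, gave 1 higher and 2 lower (percentile 48.8), with Cxcl12 at least 10.2-fold lower. The common lineage antigens had 0 of 5 called in that comparison and 6 of 8 higher, with a median of 1.86, in Lin+ cells against LT-HSC, where the list did not stand apart when only values well above background were used (percentile 95.2).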
